A study of Homo sapiens with 4 samples.

How the data were processed

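RNA of 4 samples was measured on 2 Agilent 2-colour expression arrays, 1 array per cell line. Per the labels' protocols, RNA was extracted with Trizol, reverse transcribed from a T7 primer and labelled with Cy3 or Cy5, and per the submitters' processing notes the scans were read with Agilent Feature Extraction 12.0.3.1. The scanner files of a line's DMSO and lenalidomide samples were identical, so each was read once, with Cy3 as DMSO and Cy5 as lenalidomide, as in the labels. Both arrays came from 1 slide, so no batch could be tested apart from the line.

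The authors deposited mean spot signals and median local backgrounds as linear intensity values that were not normalized, per the file headers. They also deposited processed signals, intensity values that Feature Extraction had background-subtracted and dye-normalized, and the log10 ratio of Cy5 over Cy3 made from them, per the file headers. A p-value per spot from the software's error model stood in the deposited files as well and was used as a filter in an alternative. A value table of 62969 rows held linear intensities equal to the processed signals of each sample's channel. Its medians were 10.2 for KMS12 DMSO, 9.68 for KMS12 lenalidomide, 9.07 for MM.1S DMSO and 8.33 for MM.1S lenalidomide. Its scale and direction followed from that match, and it was not centred further.

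Ratios were computed from mean signals and median backgrounds with limma 3.58.1 in R 4.3.3. Backgrounds were corrected with normexp at an offset of 50, which compresses ratios of dim spots, and each array was normalized by loess with control spots at weight 0. Spots with an outlier flag were left out, 131 on the KMS12 array and 155 on the MM.1S array, and 0 spots were saturated. Spots of 1 probe were averaged, which left 58201 probes, and each gene was represented by its brightest probe. Names came from the accession for 31104 probes, from the symbol for 3366 and from a synonym for 496, through the RefSeq names table of GRCh38, used for names alone, and the file's name was kept for 23235. Probes whose name was the probe's own ID, 1507, were left out. A gene counted as measured when both channels were well above background.

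The median signal of spots before correction was 41.9 in KMS12 DMSO over a background of 25, 82.9 in KMS12 lenalidomide over 67, 42.3 in MM.1S DMSO over 25 and 81.7 in MM.1S lenalidomide over 66. Probes printed 10 times had a median SD between spots of 0.04 (log2) on both arrays, which is technical spread within an array and not between cultures. Spike-in controls gave observed over expected log ratios with a slope of 0.827 on the KMS12 array and 0.819 on the MM.1S array, per the file headers. The intercepts there were 0.0999 and 0.105 (log10), or 1.26-fold and 1.27-fold. Both lay above 0, so the controls do not exclude an offset between the dyes that both arrays share.

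Each line's response was described by size, at 2-fold, since 1 array gives no residual. The response common to both lines was tested with limma (an intercept over the 2 arrays, eBayes, Benjamini-Hochberg at 0.05), two-sided. Nothing in the labels names separate cultures, so the spread is that between the lines. The difference between lines and the baseline difference were described by size, the latter in the Cy3 channel after Aquantile. The 27 gene lists, fixed before the data were examined, were described by the median with its percentile among 10000 random lists matched on intensity in 10 bins, and no correlation between genes was modelled. Named genes followed a rule also set before the data were examined. It took the 12 highest and 12 lowest ratios per line among genes with a symbol and at least median brightness, 10 and 10 for the shared response, 8 and 8 for the difference, 10 and 10 for the baseline, up to 4 members of each list, up to 3 genes per line and direction measured in 1 channel, and 12 genes of the drug's pathway and the lines' markers.

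The shared test was checked on 20 simulations with 200 changed genes among 16168. At 2-fold all changed genes were recovered in each, and at 1.5-fold a median of 100% (lowest 95.5%). At the smallest simulated fold, close to the median absolute mean of the shared calls (0.33), a median of 67.9% was recovered (29.9% to 83.6%), so a gene of that size that did not pass may have been missed. The share of false calls had a median of 8.05% and ran from 1.32% to 26.3%, above the nominal 5% in most simulations. Calls of the shared response near the threshold are therefore less certain than their adjusted p states. No dye effect common to both arrays was simulated, so the share of false calls leaves out those from dye.

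Alternatives were the processed signals, no background correction, an offset of 16, median centring, bright genes alone, no filter on measured genes, the median of a gene's probes, the value table, other moderation, scaling between arrays, a 1.5-fold rule, the software's p-value, the lenalidomide samples for the baseline and list means. A fit on base composition was added after the data had been seen. Splits of the samples were not tested, since no group held 3 samples.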

Results

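Gene expression was compared between lenalidomide and vehicle in KMS12 and MM.1S, both established human myeloma cell lines. Lenalidomide binds cereblon, the substrate receptor of an E3 ubiquitin ligase, and directs the ligase to the transcription factors IKZF1 and IKZF3. The arrays measured RNA, not the degraded proteins. Cells had received 10 uM lenalidomide or 0.1% DMSO for 24 h. The 4 samples formed 4 groups of 1 (KMS12 with DMSO, KMS12 with lenalidomide, MM.1S with DMSO and MM.1S with lenalidomide), so no group had replicates. The samples of a line shared 1 array, with the DMSO RNA in Cy3 and the lenalidomide RNA in Cy5 on both arrays. Without a dye swap, a dye effect of a probe adds to the drug effect within each line and in the response common to both lines. It cancels in the difference between lines as far as both arrays share it. Of 60901 spots that were not controls, 47.7% were well above background in KMS12 DMSO, 44.3% in KMS12 lenalidomide, 47.8% in MM.1S DMSO and 43.2% in MM.1S lenalidomide. The number of arrays, 2, limits the precision. Values below are log2 ratios of lenalidomide over DMSO unless another quantity is named.

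The first question was which transcripts moved in both lines. DEPP1, a stress-responsive gene regulated by FOXO factors, rose by a mean of 0.99 ± 0.06 (SD, n = 2 lines; limma adjusted p = 2.77e-06). TSC22D1 rose by 0.88 ± 0.15 and the growth factor precursor GRN by 0.80 ± 0.14. ISG20, an interferon-inducible exonuclease, had the lowest mean among the named genes, -0.72 ± 0.03 (adjusted p = 3.36e-05), and fell in both lines. MYC, a driver of growth in myeloma, fell in both lines, with -0.49 in KMS12 and -0.42 in MM.1S (mean -0.46 ± 0.05, adjusted p = 0.00168). In all, 459 genes rose and 171 fell among 16168 genes measured on both arrays, and each of these 630 had the same sign in both lines, which a test of the mean against the spread between lines favours. The mean reached 1.5-fold in 30 of the genes that rose and in 1 that fell. The counts depended on the processing, with 6664 up and 56 down under median centring, and 111 and 35 with a normexp offset of 16. The test took the 2 lines as replicates with 1 residual degree of freedom, and in 20 simulations of it the false share of calls had a median of 8.05% and ran from 1.32% to 26.3%. The simulations held no dye effect common to both arrays, so that share leaves out false calls from dye. With the processed signals of the scanner software 0 genes passed limma's adjusted threshold. There 2108 genes had an unadjusted p under 0.05, against 3186 in the main setting. Of the 630 genes 629 kept their sign there, but the signals come from the same spots, so this is no independent support.

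A second probe that does not overlap the first was measured for 159 of the 630 genes, and its mean had the same sign for 85.5% of them and a median of 0.357 of the first probe's. The first probe was the brightest and had passed, which by itself can lower that ratio. Other genes that rose in both lines included DSE, a dermatan sulfate epimerase, by 0.79 ± 0.46, the collagen chaperone SERPINH1 by 0.77 ± 0.06 and the junction protein gene CGN by 0.77 ± 0.11. The actin regulator WASF1 rose by 0.74 ± 0.03. LGALS1, which encodes galectin-1, had 1.01 in KMS12 and 0.39 in MM.1S, and the transcriptional inhibitor ID2 had 0.74 and 0.64. CASP1, an inflammatory caspase, rose by 0.64 ± 0.25. The genes that fell included HSPG2, with a mean of -0.58 ± 0.17, BCDIN3D with -0.57 ± 0.02, SSBP4 with -0.55 ± 0.16 and PPP2R3C with -0.55 ± 0.16. PRR7 had -0.54 ± 0.09, the mitochondrial protease gene OMA1 -0.51 ± 0.27, SMIM27 -0.48 ± 0.05 and CCDC167 -0.46 ± 0.18. ID1, an inhibitor of DNA binding related to ID2, fell with -0.22 in KMS12 and -0.74 in MM.1S. With the median of all probes of a gene, well above background or not, in place of the brightest, the mean of MYC was -0.15 and that of HSPG2 was -0.07, and neither passed, but the brightest was the only probe of each that was well above background in all samples; MYC and CCDC167 did not pass under median centring either. With robust and trended moderation DSE and LGALS1 did not pass, and of all 58 named genes past the test 33, among them LGALS1, OMA1, ID1 and CCDC167, did not pass with a smaller normexp offset of 16.

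**Figure D1:**
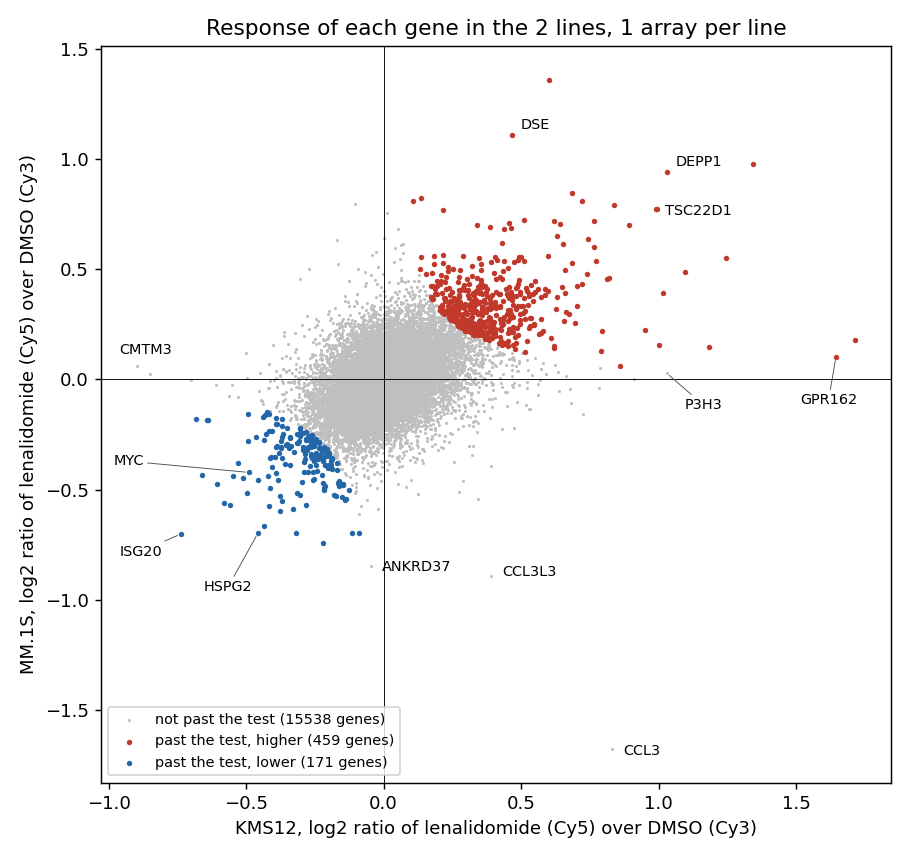
Log2 ratio of lenalidomide over DMSO in KMS12 (horizontal) and MM.1S (vertical) for 16168 genes measured on both arrays, 1 point per gene, with 459 genes that rose in red, 171 that fell in blue and the rest in grey. DEPP1 lies at 1.03 and 0.94, and CCL3 at 0.83 and -1.68, on opposite sides of 0.

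Among genes with a symbol and at least median brightness in KMS12, GPR162, an orphan receptor gene, had the largest ratio, 1.65. P3H3, a collagen prolyl hydroxylase gene, DEPP1 and LGALS1 were also at least 2-fold higher in the lenalidomide sample, with 1.03, 1.03 and 1.01. TSC22D1 had 0.99, TMEM132A 0.97, GRN 0.89, the chemokine receptor gene CCR2 0.84, CASP1 0.82, ARHGAP9 0.79 and YPEL5 0.79. The chemokine gene CCL3 was higher as well, with 0.83. The lowest ratios among such genes were those of G0S2, an inhibitor of lipolysis, with -0.99, CMTM3 with -0.90, ISG20 with -0.74, ADGRB1 with -0.70 and WNK2 with -0.68. KCNH2 had -0.64, PLAAT3 -0.61, MICALL2 -0.56 and DBN1 -0.55. Among 18273 measured genes, 14 were at least 2-fold higher and 0 at least 2-fold lower. At 1.5-fold the counts were 88 and 13. With 1 array the ratios had no test or replicate check. The scanner software's processed signals gave 73 higher and 12 lower genes at 2-fold.

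In MM.1S the highest ratios among genes with a symbol and at least median brightness belonged to CXCL10, an interferon-inducible chemokine gene, with 1.83, the nucleotide receptor gene P2RY6 with 1.70 and EMP2 with 1.39. DSE had 1.11. HLA-DRA, the alpha chain of an MHC class II molecule, had 0.99, and the integrin gene ITGB5 0.87. SECTM1 had 0.83, CGN 0.85, SERPINH1 0.81, MTMR10 0.81 and SHTN1 0.78. CXCL10, P2RY6, EMP2, HLA-DRA, ITGB5, SECTM1 and SHTN1 were not well above background in both channels of KMS12. CCL3 was the lowest such gene, with -1.68, followed by its close paralog CCL3L3 with -0.89 and by ANKRD37 with -0.85. ID1 had -0.74, and IRF4, a transcription factor on which myeloma cells depend, -0.58. The pseudogene PMS2P5 had -0.57. Among 17910 measured genes, 9 were at least 2-fold higher and 1 at least 2-fold lower. At 1.5-fold the counts were 71 and 18. No test was possible with 1 array, and the processed signals gave 87 higher and 23 lower genes at 2-fold.

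The cereblon pathway and the plasma cell regulators were read in both lines because of the drug's known target. CRBN, which encodes cereblon, had -0.04 in KMS12 and -0.04 in MM.1S. IKZF1 had 0.31 and -0.11, and IKZF3 0.39 and -0.18, in KMS12 and MM.1S. A dimmer probe gave 0.21 and 0.03 for IKZF1, and 0.17 and -0.004 for IKZF3, also lower in MM.1S than in KMS12. The MM.1S ratios of -0.11 and -0.18 themselves rest on the brighter probe of each gene. The dimmer IKZF1 probe had a mean log2 intensity of 6.44 in MM.1S, where the normexp offset compresses ratios. Of 15 measured genes of the cereblon ligase and its substrates, 0 passed limma's adjusted threshold over all genes, 4 had an unadjusted p under 0.05 and 2 passed upwards adjusted over the list alone. The list's median was 0.08, at percentile 97.7, against 0.02 in KMS12 and 0.02 in MM.1S, at percentiles 66.94 and 67.5, and 0.29 and 0.23 under median centring. The largest absolute means there were those of ZNF692, 0.26 ± 0.14, and DDB1, 0.25 ± 0.11. IRF4 had -0.08 in KMS12 and -0.58 in MM.1S and did not pass (adjusted p = 0.0608). XBP1, the secretory regulator of plasma cells, fell, with -0.22 and -0.50 (adjusted p = 0.0168), and its mean was -0.03 and did not pass under median centring. XBP1 was the only 1 of 17 measured plasma cell identity genes to pass over all genes, and adjusted over the list alone 2 passed upwards and 3 downwards. TNFRSF17, which encodes BCMA, had -0.06 and -0.44, SLAMF7 0.26 and -0.02, CD38 0.01 and 0.29, GPRC5D 0.11 and 0.39, and SDC1 -0.05 and -0.05, none past the test. CDKN1A was measured in MM.1S, with 0.11, and was not well above background in both channels of KMS12.

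Of 27 gene lists 6 had a median in the outer 2.5% of random lists at either end, and the antigen presentation lists had the highest medians. Of 18 measured MHC class I presentation genes, 5 rose, 0 fell and 13 did not pass, and adjusted over the list alone 10 passed upwards and 1 downwards. HLA-F rose by 0.42 ± 0.05, the peptide loading factor TAPBP by 0.40 ± 0.02 and HLA-G by 0.33 ± 0.03. HLA transcripts are similar in sequence, and the 12 genes of the list outside the HLA family had a median of 0.04 at percentile 84.5. Of these, TAPBP and PSMB8, the latter with 0.31 in KMS12 and 0.25 in MM.1S, were among the 5 that rose. TAPBP did not pass with the median of a gene's probes. The list's median was 0.18, at percentile 100 of 10000 random lists of the same size and intensity, with 0.26 in KMS12 and 0.10 in MM.1S (0.54 and 0.40 under median centring). Of 9 measured MHC class II genes 1 rose over all genes, HLA-DMB, by 0.64 ± 0.01, and 4 passed upwards adjusted over the list alone. HLA-DRB1 had 0.07 in KMS12 and 0.62 in MM.1S, HLA-DMA 0.06 and 0.55, HLA-DPA1 0.13 and 0.33, and the class II activator CIITA -0.16 and 0.52. Over the 9 class II genes measured in both lines the median was 0.06 in KMS12 and 0.33 in MM.1S, and the median of their differences was 0.21, which was not tested. CIITA, HLA-DMA and HLA-DPA1 were dim in KMS12, with mean log2 intensities of 6.36, 6.51 and 6.82, where the normexp offset compresses ratios.

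Of 21 measured immune ligands and therapy antigens 3 rose and 1 fell, against 5 and 2 adjusted over the list alone, with a median of 0.12 at percentile 99.97. The costimulatory ligand TNFSF9 rose by 0.33 ± 0.09, CD58 by 0.30 ± 0.07 and ICAM1 by 0.27 ± 0.01, whereas ICAM2 fell, with -0.38 ± 0.04. Of 18 adhesion and homing receptors 3 rose, namely the integrins ITGB7, by 0.63 ± 0.02, and ITGB1, by 0.52 ± 0.02, and the selectin ligand SELPLG, by 0.29 ± 0.03. Adjusted over the list alone 6 passed upwards and 0 downwards. Of 13 measured cytokines and chemokines 0 passed limma's threshold over all genes, with 6 higher and 1 lower at an unadjusted p under 0.05, and 5 passed upwards and 1 downwards adjusted over the list alone. The median of that list was 0.14, at percentile 99.91. IL15 had 0.57 and 0.05, CCL5 -0.02 and -0.59, and TNFSF10 0.37 and 0.15 in KMS12 and MM.1S. Of 18 NF-kB targets NFKBIA, by 0.30 ± 0.21, and ICAM1 rose, and 5 passed upwards and 1 downwards adjusted over the list alone. Over the 18 genes the KMS12 median was 0.10. Over all genes of that list measured in a line it was 0.15 over 20 in KMS12, at percentile 100, and -0.06 over 19 in MM.1S, at percentile 5.28, where it was 0.13 under median centring. ICAM2 did not pass under median centring, and ICAM1, SELPLG, NFKBIA and IFITM2 did not pass without background correction. Of 21 interferon-stimulated genes measured on both arrays 2 rose, IFITM1 by 0.39 ± 0.25 and IFITM2 by 0.35 ± 0.30, and 2 fell, 1 of them ISG20. The list's median was 0.09 over 37 genes in MM.1S, at percentile 99.4, 0.02 over the 21 of them measured on both arrays, and -0.02 over 21 genes in KMS12, at percentile 18.26, where it was 0.08 under median centring. Adjusted over the list alone the counts were 5 and 3, and IFIH1, a sensor of viral RNA, had 0.66 and 0.02.

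Proliferation genes gave few calls. Of 29 measured G1/S and DNA replication genes 0 passed limma's threshold over all genes or adjusted over the list alone, with 2 higher and 7 lower at an unadjusted p under 0.05. Their median was -0.13 in KMS12 (0.14 under median centring), at percentile 0, and 0.01 in MM.1S, at percentile 65.56. CDC45 had -0.24 and -0.19, MCM7 -0.25 and -0.14, and MCM4 -0.28 and -0.07. The list's median over both lines, -0.06, was 0.19 under median centring, which moved the median of all measured genes by 0.16 in KMS12 and 0.14 in MM.1S and under which each of the 27 lists had a median above 0 in each line. Of 31 G2/M genes 0 passed either way, with 2 at an unadjusted p under 0.05 and a median of 0.00, and CDK1 had -0.20 and -0.26. Of 27 MYC and ribosome biogenesis genes MYC alone fell, over all genes and adjusted over the list alone. That list's median was -0.09 in KMS12 and -0.01 in MM.1S, and it was above 0 under median centring (0.25 over both lines). Of 5 CDK inhibitors CDKN1C rose, by 0.30 ± 0.10, and 2 passed upwards adjusted over the list alone. CDKN1C did not pass without background correction.

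Among stress and survival genes, 3 of 18 p53 targets rose and 1 fell, against 4 and 1 adjusted over the list alone. TP53INP1 rose by 0.52 ± 0.26, GADD45A by 0.38 ± 0.02 and SESN1 by 0.30 ± 0.03, whereas PLK3 fell, with -0.26 ± 0.02. Of 15 BCL2 family genes the proapoptotic BMF rose by 0.58 ± 0.11 and the proapoptotic HRK fell, with -0.31 ± 0.06, and 2 passed in each direction adjusted over the list alone. In the ATF4 and amino acid list, ATF3 rose by 0.47 ± 0.14 and DDIT4 by 0.39 ± 0.26, while TRIB3, with -0.34 ± 0.13, and CEBPB, with -0.28 ± 0.03, fell, and the other 14 measured genes did not pass, with 2 in each direction adjusted over the list alone. PLK3, HRK, TRIB3, CEBPB and BNIP3L did not pass under median centring, and ATF3, BNIP3L, PRDX1 and PPIA did not with the median of a gene's probes. Of 18 unfolded protein response genes XBP1 fell and 17 did not pass, with 1 in each direction adjusted over the list alone. Of 21 oxidative stress genes 4 rose, GPX1 by 0.34 ± 0.02, FTH1 by 0.31 ± 0.16, HMOX1 by 0.29 ± 0.00 and PRDX1 by 0.27 ± 0.05, and 5 passed upwards adjusted over the list alone. Of 23 hypoxia and glycolysis genes ADM rose by 0.58 ± 0.20 and BNIP3L fell, with -0.36 ± 0.19, against 1 and 2 adjusted over the list alone. STARD4, by 0.34 ± 0.01, was the 1 of 22 cholesterol synthesis genes that rose, with 1 in each direction adjusted over the list alone. Of 23 heat shock and proteasome genes 0 passed limma's threshold either way, with 4 at an unadjusted p under 0.05. Of 17 reference genes ACTB rose by 0.29 ± 0.07 and PPIA by 0.27 ± 0.03, 15 did not pass, 4 passed upwards and 1 downwards adjusted over the list alone, and the list's median was 0.07 at percentile 97.3.

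**Figure D2:**
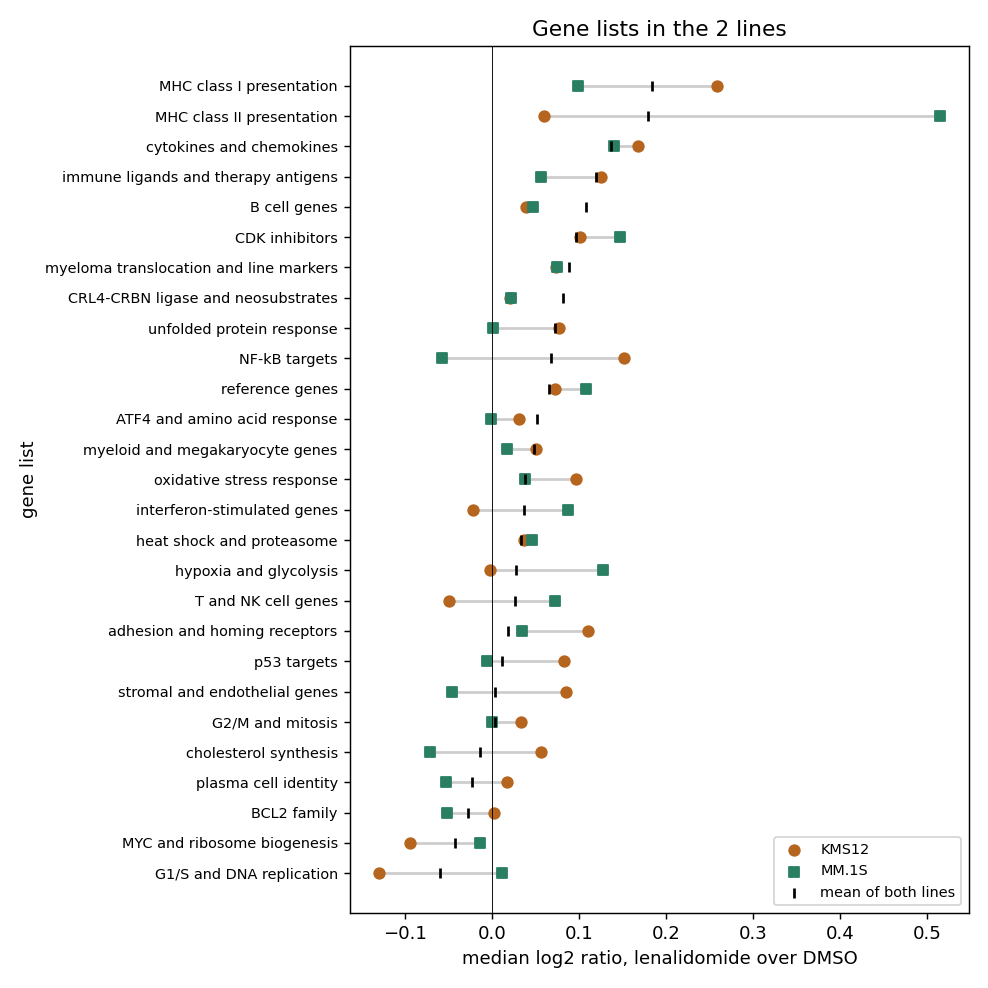
Median log2 ratio of lenalidomide over DMSO (horizontal) for 27 gene lists (vertical), in KMS12 (circles) and MM.1S (squares) over the genes measured in that line, and for the mean of both lines (bars) over the genes measured in both. MHC class I presentation had the highest median of the means, 0.18, and G1/S and DNA replication the lowest, -0.06, which was 0.19 under median centring.

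Markers of other cell types gave few calls. Of 6 measured stromal and endothelial genes SPARC rose by 0.37 ± 0.09, with 1 gene in each direction adjusted over the list alone. Of 6 myeloid and megakaryocyte genes and of 5 T and NK cell genes 0 passed limma's threshold either way, and 0 had an unadjusted p under 0.05. Of 6 B cell genes 0 passed over all genes and 2 were higher and 1 lower at an unadjusted p under 0.05, and 2 B cell genes passed upwards and 1 downwards adjusted over the list alone. The B cell factor SPIB had -0.53 in KMS12 and -0.08 in MM.1S, and FCRLA 0.52 and -0.01. Of 11 myeloma translocation and line markers ITGB7 rose, and 2 passed upwards adjusted over the list alone.

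The response was next compared between lines, where a dye effect common to both arrays cancels. CCL3 differed the most, with -2.51 for MM.1S minus KMS12, and CCL3L3 by -1.28. The other 3 genes with at least a 2-fold difference were GPR162, with -1.54, SDSL, with -1.53, and TNNT1, with -1.03, the last 2 named after their values were seen. GPR162 and TNNT1 were dim in MM.1S, with mean log2 intensities of 6.51 and 6.30, and CCL3L3 was dim in KMS12, with 6.79. The normexp offset compresses ratios of such dim spots, so a small ratio there says little. P3H3 had 1.03 in KMS12 and 0.03 in MM.1S. MM.1S was also below KMS12 for the glucocorticoid-induced TSC22D3, with -0.91, ANKRD37, with -0.80, the apoptosis inhibitor BIRC3, with -0.79, the metallothioneins MT2A, with -0.78, and MT1L, with -0.75, and YPEL5, with -0.74. CMTM3 had 0.96, ADGRB1 0.70 and CIITA 0.69. Of these, CMTM3 and ADGRB1 were dim in MM.1S, with mean log2 intensities of 6.46 and 6.40, and CIITA was dim in KMS12, with 6.36. Among genes with a symbol and at least median brightness over both arrays, a limit CMTM3 did not meet, the highest differences were those of PNPLA7, 0.80, BLVRA, 0.74, MTMR10, 0.70, DSE, 0.65, and TNFRSF25, 0.56. IFITM3 had 0.55, TRPM2 0.55 and WNK2 0.50. In all 5 genes were at least 2-fold lower and 0 at least 2-fold higher in the response of MM.1S. With 1 ratio per line the difference was not tested, and the processed signals gave 51 lower and 58 higher genes.

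The lines were far apart before treatment. In the DMSO samples the plasma cell gene JCHAIN was higher in MM.1S by 7.20, the transcription factor MAF by 6.49 and CCL3 by 6.31, while CCND1, which encodes cyclin D1, was lower in MM.1S, with -3.42. MM.1S is known for a translocation that activates MAF and KMS12 for one that activates CCND1. Histone genes led the named genes, with H4C3 at 10.25 and H4C13 at 7.62, followed by SNAR-G1 at 7.31. A second H4C13 probe had a mean log2 intensity of 8.96 in KMS12 and 8.91 in MM.1S. RASA3 had 6.28, NLRP7 6.23, GPAT2 5.81 and SFN 5.79. The lowest in MM.1S were the lipid receptor gene S1PR4, with -8.12, S100A4, with -7.31, MDK, with -7.23, ARHGEF10L, with -6.23, and RASGRP2, with -6.05, of which 1 dim probe had a mean log2 intensity of 6.88 in KMS12 and 6.61 in MM.1S. ETFB had -6.04, CD81 -6.00, ICAM3 -5.98, KREMEN2 -5.96 and MLLT11 -5.88. The plasma cell genes SLAMF7 and SDC1 were higher in MM.1S by 4.09 and 3.88. Of 17896 genes measured in both DMSO samples, 1219 were at least 2-fold higher and 1510 at least 2-fold lower in MM.1S, with no test. The processed signals gave 1995 and 2350. In the lenalidomide samples the counts were 1215 and 1506, and 2359 of 2596 such genes measured in all 4 samples differed at least 2-fold the same way there. Those samples are the other channel of the same arrays and spots, so this is no independent support.

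Some genes were well above background in 1 channel of an array. In KMS12 this held for 293 in the lenalidomide channel alone and for 1755 in the DMSO channel alone. In MM.1S the counts were 227 and 2199. Negative controls had an SD of 1.91 in Cy3 and 3.33 in Cy5 on the KMS12 array, and of 1.70 and 3.16 on the MM.1S array. A noisier Cy5 background by itself can raise the counts in the DMSO channel alone, so these do not show lost expression. For genes measured in 1 channel a bound is given, as the brighter channel over the higher of the dim probe's own signal and the lowest signal well above background, both after loess and Aquantile. For the DMSO channel alone it was over 1 in 1518 of the 1755 genes in KMS12 and in 1665 of the 2199 in MM.1S. In KMS12 GAD2 was at least 1.44-fold, NEURL3 at least 1.38-fold and DOK4 at least 1.30-fold higher with lenalidomide. PARM1 and LY6D were each at least 1.23-fold lower, and BHLHA15 had a log2 signal of 6.47 with DMSO over a floor of 6.15. In MM.1S PLEKHG3 was at least 1.85-fold, and MMP12 at least 1.55-fold higher, and KITLG had a log2 signal of 6.80 with lenalidomide over 6.21 with DMSO. SCN3B was at least 1.64-fold, KCNMB2 at least 1.39-fold and GARIN1B at least 1.38-fold lower. No such bound reached 2-fold in either line, and all are open to dye bias.

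Probe positions are on GRCh37 (hg19), as in the array files. The DEPP1 probe lies on chromosome 10 from 45471710 to 45471769, the ISG20 probe on chromosome 15 from 89198784 to 89198843, the MYC probe on chromosome 8 from 128753268 to 128753327, the CCL3 probe on chromosome 17 from 34415605 to 34415664 and the HLA-DMB probe on chromosome 6 from 32902504 to 32902563. No annotation of that build was used, so exons and untranslated regions are not given. Log2 ratios of lenalidomide over DMSO from probes of 1 named gene did not oppose each other at 0.5 or more in either line. The SD of log2 ratios was 0.15 in KMS12 and 0.16 in MM.1S, so that rule could seldom be met. Probes did oppose at smaller sizes, as for PRDX1, whose second probe had -0.12 and -0.08 against 0.31 and 0.24.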

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

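The rule for an opposite response (ratios of opposite sign in the lines, each past 3 times the spot SD, and a difference of at least 1.5-fold) was set after the ratios had been seen. The differences were not tested, since each line had 1 array.

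The chemokine gene CCL3 was higher with lenalidomide in KMS12 (0.83) and lower in MM.1S (-1.68), a difference of -2.51, and CCL3L3, on a separate spot, had 0.39 and -0.89, a difference of -1.28. CCL4L2, of a related chemokine and named after its values were seen, had 0.32 and -0.34. A defect of a single spot would not give all of these, but CCL3 and CCL3L3 are near-identical, so their probes are not independent readings. The KMS12 log2 signals with DMSO and lenalidomide were 6.24 and 6.56 for CCL4L2, and 6.56 and 6.95 for CCL3L3. The lowest well above background there were 6.12 and 6.15. The KMS12 ratio of CCL4L2 thus lies near the floor, and that of CCL3L3 not far above it. A spot or probe defect was tested on a second probe that does not overlap the first, which 1 of the 20 opposite genes had, SNORD3B-1 (named after its values were seen). Its second probe gave 0.145 of the first probe's difference, with the same sign, and 1 gene is too few to decide, so a probe defect and a biological difference between the lines both stay open.

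PNPLA7 was lower in KMS12 (-0.17) and higher in MM.1S (0.63), a difference of 0.80. The metallothionein genes MT2A and MT1L were higher in KMS12 and lower in MM.1S, with differences of -0.78 and -0.75. MT1E had 0.17 and -0.22, but MT1X was higher in both, with 0.22 and 0.06 (both named after their values were seen). CIITA was lower in KMS12 (-0.16) and higher in MM.1S (0.52), a difference of 0.69. Its KMS12 log2 signals were 6.43 with DMSO and 6.27 with lenalidomide. The lowest well above background there were 6.12 and 6.15, so its KMS12 ratio lies near the floor.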

How the results depend on the processing

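The fit on base composition was chosen after seeing the data. With the processed signals, and alike with the deposited value table, 2-fold counts were 73 higher and 12 lower in KMS12, 87 and 23 in MM.1S, 58 higher and 51 lower for the difference, 1995 and 2350 for the baseline, and 0 and 0 genes passed the shared test. There the estimated prior degrees of freedom were 2.59 against 14.4 in the main setting, the smallest adjusted p was 0.332 and 2108 genes had an unadjusted p under 0.05. With an offset of 16 the counts were 22 and 1 in KMS12, 18 higher in MM.1S, 111 up and 35 down in the shared test, and 3 and 10 for the difference. Median centring gave 32 higher genes in KMS12, 22 in MM.1S, and 6664 up and 56 down in the shared test, so 99.2% of calls were up against 72.9%, and the G1/S median turned to 0.19. No background correction gave 62.4% up, 1 gene lower in KMS12 and 1 higher for the difference. Bright genes alone gave 7 higher in KMS12, 351 down in the shared test (62.9% up), 2 lower for the difference and 1001 lower at baseline. Without a filter the difference held 12 and 10 genes. The median of probes gave 2 lower genes in MM.1S. The 1.5-fold rule gave 88 and 13 in KMS12 and 71 and 18 in MM.1S. Robust and trended moderation gave 889 up and 531 down, scaling between arrays 257 down, and the fit on base composition 360 down (64.8% up). The cause of these moves was not tested, except that a looser size rule raises, and leaving out dim genes lowers, a count by size by construction.

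With the smaller offset 33 of the 58 named genes past the shared test no longer passed, against 9 under median centring, 8 with the median of probes, 5 without background correction and 2 with robust and trended moderation. The number of lists in the outer 2.5% at either end was 6 and lay between 5 and 9 elsewhere. Of the 630 shared genes 482 still passed without background correction, 146 with an offset of 16, 501 under median centring and 476 with the median of probes, all in the same direction. Leaving out either line left 1 ratio and no test. Leaving out saturated spots was not run, since 0 were saturated. The shared test is paired by line, since it uses the ratio of the 2 channels of each array. Signal over background limits dim genes, as 44.3% and 43.2% of Cy5 spots were well above background.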

Other observations

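The 2 tests of the MHC class I list were chosen after its median had been seen.

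Hypoxia and glycolysis genes had a median of 0.13 over 25 genes in MM.1S, at percentile 99.95, while in KMS12 the median over 23 genes lay at percentile 44.75; under median centring the medians were 0.30 and 0.28. The MM.1S minus KMS12 difference of the plasma cell identity genes had a median of -0.13, at percentile 0.04, with TNFRSF17 at -0.06 in KMS12 and -0.44 in MM.1S, and was not tested; under median centring the list's own medians were 0.22 in MM.1S and 0.19 in KMS12, the other order from -0.05 and 0.02. The myeloma translocation and line markers had a median of 0.09 over 11 genes, with BCL2 at 0.39 and 0.14.

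The genes that passed the shared test may reflect the dyes, since lenalidomide was Cy5 on both arrays. Base composition and intensity took up 1.76% of the variance of the mean ratio, and 99.4% of the 630 genes still passed after the fit was removed. This argues against a linear trend with base composition as the whole cause. Loess had already removed the trend with intensity on each array, so for intensity the fit decides nothing. Among 159 such genes with a second probe that does not overlap the first, the second probe's mean was a median of 0.357 of the first's, and 85.5% had the same sign, against 56.5% of 2986 genes that had not passed. The latter mostly have means nearer 0, so a lower share there follows from selection and decides nothing. The first probe was the brightest and had passed, which by itself can lower the ratio. The ratio lies between the bounds set for a dye effect of single probes and for none, so the 2 cannot be told apart without a dye swap, which the design lacks. With the sign of 1 array turned 2 genes passed, a count that a dye effect common to both arrays would give as well.

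The higher MHC class I list could be 1 signal shared by HLA paralogs. Without the HLA genes the other 12 members had a median of 0.04, at percentile 84.5, the outcome set for that explanation. A change in the HLA genes themselves gives the same values and stays open. Of those 12 members TAPBP (0.42 in KMS12 and 0.39 in MM.1S) and PSMB8 (0.31 and 0.25) passed the shared test, while ERAP1 had -0.12 and -0.25. A signal shared by HLA paralogs would not account for PSMB8 or for the brightest TAPBP probe. Dimmer TAPBP probes had 0.17 in KMS12 and -0.08 in MM.1S, and 0.09 and -0.08. The rise of TAPBP in MM.1S thus rests on the brightest probe alone. After the fit on base composition the list lay at percentile 100 with a median of 0.20, which argues against that trend as the cause.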
